A study of Arabidopsis thaliana with 24 samples.

How the data were processed

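The series comprises 24 single-colour arrays of Arabidopsis thaliana, 6 ecotypes at 2 CO2 levels with 2 replicate arrays each. Per the labels, plants grew for 38 days at 20 °C and 60% humidity with 10 h of light a day, at 130 µmol of photons per square metre and second for 9 h and 660 for 1 h, and 800 ng of TRIzol-extracted RNA was amplified and labelled with Cy3. The arrays carry 34262 probes of 60 bases other than controls: 26649 each name 1 gene locus, 7322 name transcription units without a gene annotation, and 291 name several loci. Of the loci, 26171 were matched to the given table of reference genes, and 10292 have a symbol there; the others are named by locus. The probe annotation predicts cross-hybridisation for 1393 probes. Gene positions are the spans in the array's annotation. No genome sequence was given, so the assembly could not be checked and the place of a probe within exons or untranslated regions was not determined.

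The deposited scanner files hold spot values in intensity units, made by the authors with Agilent Feature Extraction 9.5.3.1 (per the file headers), which subtracts background and corrects trends within an array but, as tested on the values, does not scale arrays to each other. The deposited series matrix holds the natural log of the same processed signal. It equals the natural log of the processed signal of each array to within 5.0e-09, with no scaling or centring between arrays, so that nothing about its scale stays unknown, and its median per array ran from 3.75 to 5.20. Because arrays differ in brightness, the unscaled values move the median CO2 difference of all genes to -0.24 (log2), against 0.01 after scaling. Near background the size of a difference depends on how background is corrected, and a probe matched to 1 ecotype can read lower in another.

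In R 4.3.3 with limma 3.58.1, the processed signal was taken to log2 and the 75th percentile of each array over its non-control probes was subtracted. A gene was tested if its probe was well above background on both arrays of at least 1 of the 12 groups, which left 19972 genes. Each locus has 1 probe, so no choice between probes arose. A linear model with 12 group means was fitted (lmFit), with eBayes and an intensity trend, and p values were adjusted by the Benjamini-Hochberg method over genes, with a threshold of 0.05; all tests were 2-sided. The model left 12 residual degrees of freedom. The contrasts were the mean CO2 difference over 6 ecotypes, the CO2 difference in each ecotype, its interaction with ecotype and the differences between ecotypes. Growth classes were compared on 1 value per ecotype, 3 against 3, by limma. Where a probe was not well above background on any array of a group, the difference is given as a bound: the mean of the brighter group over the mean, in the dim group, of the higher of the lowest signal well above background on that array and the dim probe's own signal. Values are log2 differences with the standard error of the model unless stated otherwise.

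Fixed lists of genes, 27 in all, were tested for the mean CO2 difference and for the class differences in CO2 effect and in level at each CO2 level. They were not tested for single ecotypes, the interaction or the ecotype differences. Camera (preset correlation 0.01, and an estimated correlation as an alternative) and fry were used where at least 5 members were measured, with adjustment over the lists. The flower markers had too few, and the control genes served as values only. Genes named in the text follow a rule. For the mean CO2 difference they are the 12 largest rises and 12 largest falls that passed with 1 sign in all 6 ecotypes; for each ecotype's CO2 difference the 3 largest rises and 3 largest falls that passed, or the 2 smallest p; for class differences the 10 largest that passed, or, where fewer than 4 passed, the 8 smallest p; for each ecotype's level the 2 largest in each direction; and up to 4 passing members of each list. List members that did not pass over all genes were chosen for naming after their values were seen. The comparisons, lists, rule, filter and most other settings to try were fixed before the data were examined. These settings were normexp background correction (offset 50), quantile normalization, the series matrix, no filter or a strict filter, no trend, spots with outlier flags left out, array weights, blocks for replicate number, ecotype by replicate number, slide and scan day, a random block for CO2 level by replicate number, fits on 1 ecotype alone, arrays or ecotypes as the unit, and leaving out each array and each ecotype. Removal of 2 arrays, exchange of their labels, that exchange together with the scan day block, and the scan day block for the gene lists, also with an estimated correlation, were added after the data were examined.

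The arrays lay on 7 slides and were scanned on 4 days. Day 1 and day 3 each held 6 elevated and 2 ambient arrays, day 2 held 2 ambient and day 4 held 6 ambient ones, and 1 slide held both CO2 levels of 1 ecotype. All elevated arrays of replicate 1 were scanned on day 1, all of replicate 2 on day 3, and all ambient arrays of replicate 2 on day 4. The pipeline was tested on simulated data with known changes in 100 genes per size. The simulated noise was independent between arrays, without effects of replicate, slide or scan day. The shares of recovered and false calls that follow hold for such noise only. The mean CO2 contrast recovered 79.0% of changes of 1 log2 unit and 92.0% of changes of 2, the contrast in Bur-0 13.0% and 53.0%, the F test between ecotypes 30.0% and 74.0%, and the class contrast 0% of both; false calls made up 4.47%, 4.35% and 1.89% of the calls of these 3 in this order. No class difference in CO2 effect of the simulated sizes was found gene by gene; class differences in level were not simulated. Other groupings of the arrays, 100 with a fixed seed or all 10 for the classes, were tested to see whether they call as many genes. Probes that name several loci and control spots were left out.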

Results

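Gene expression was measured in 38-day-old Arabidopsis thaliana plants, called seedlings in the labels, of 6 natural accessions, here called ecotypes. Each ecotype was grown in ambient air, at 380 to 400 µmol CO2 per mol, or in elevated CO2, at 800 µmol per mol. Every one of the 12 combinations of ecotype and CO2 level had 2 replicate arrays, which makes 24 single-colour Agilent arrays. The study sorted the ecotypes by how much elevated CO2 speeded growth. Bur-0, Fei-0 and Sf-1 formed the class with the larger enhancement, and Col-0, Te-0 and Yeg-1 the class with the smaller one. The design text names Fei-1 where the sample labels name Fei-0, and the Col-0 samples carry Col-1 in their descriptions. The names of the sample titles are used here. Between 52.9% and 64.7% of the probes on an array were well above background, and the 75th percentile of the processed signal ran from 473 to 2178 between arrays. The number of arrays, 2 per group, limits the precision of every value. Over genes, which are not independent replicates, the correlation between the 2 replicates of a group was 0.884 for Te-0 in ambient CO2 and 0.927 for Yeg-1 in ambient CO2, and from 0.946 to 0.981 in the other 10 groups. The low values came with 2 arrays whose expression resembled the other ecotype. On 1075 genes that separated Te-0 from Yeg-1 in elevated CO2, the array labelled Te-0 ambient CO2 replicate 1 lay at 1.04 of the way from Te-0 to Yeg-1, and the array labelled Yeg-1 ambient CO2 replicate 1 lay at 0.97 of the way from Yeg-1 to Te-0 (medians over genes). Both arrays were kept as labelled, and counts of genes and lists are also given with their labels exchanged or without them where these differ by much.

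**Figure D1:**
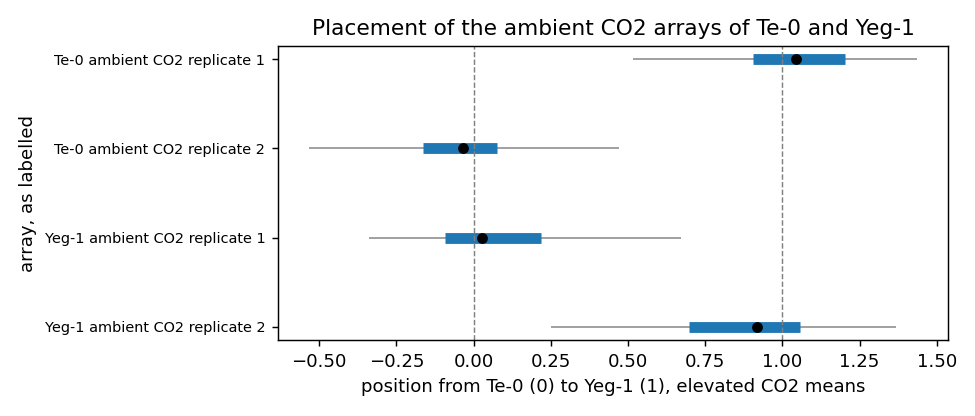
Position of the 4 ambient CO2 arrays of Te-0 and Yeg-1 on the line from the mean of the Te-0 arrays (0) to the mean of the Yeg-1 arrays (1) in elevated CO2, over 1075 genes; points are medians, thick bars the middle 50% of genes and thin lines the middle 90%. The array labelled Te-0 replicate 1 has its median at 1.04 and the array labelled Yeg-1 replicate 1 at 0.03.

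The first comparison asked which genes responded to elevated CO2 on average over the 6 ecotypes. Of 19972 genes tested, 96 differed between the CO2 levels, 57 higher and 39 lower in elevated CO2 (limma, adjusted p under 0.05). Of these, 81 moved the same way in all 6 ecotypes, 50 of them up and 31 down, and 31 changed at least 2-fold. The signs in Te-0 and Yeg-1 rest in part on the 2 arrays that resembled the other ecotype. Here and below, signs in all 6 ecotypes are those as labelled and were not counted with the labels exchanged. Among all genes 10.7% had the same sign in 6 ecotypes, against 3.12% by chance for independent values. The largest consistent rise was that of CER4, the fatty acyl-CoA reductase that makes the primary alcohols of the leaf wax (AT4G33790, chromosome 4, 16204327 to 16206665). Its normalized log2 signal was -0.22 ± 0.98 in elevated and -2.03 ± 0.98 in ambient CO2 (SD over ecotypes and replicates, n = 12 arrays each), a log2 difference of 1.81 ± 0.22 (SE, adjusted p = 0.0024). ORA59, an ethylene response factor that joins jasmonate and ethylene signals (AT1G06160, chromosome 1, 1883045 to 1883779), rose by 1.76 ± 0.35 (adjusted p = 0.0426) and was well above background on 11 elevated and 10 ambient arrays. ACO1, which makes ethylene from its precursor (AT2G19590, chromosome 2, 8483321 to 8484436), rose by 1.03 ± 0.20. FTM1, a fatty acid desaturase (AT1G43800, chromosome 1, 16580102 to 16581989), rose by 1.26 ± 0.21. The nitrate transporter NRT1.5, which loads nitrate into the xylem (AT1G32450, chromosome 1, 11715317 to 11719787), rose by 1.00 ± 0.12 (adjusted p = 0.0024). The transcription factor genes BEE3, a brassinosteroid-responsive bHLH gene, and PIL1, a shade-responsive one, rose by 1.04 ± 0.20 and 1.00 ± 0.08. PIL1 (AT2G46970, chromosome 2, 19302686 to 19304747) had the smallest p of the named genes (adjusted p = 8.18e-05). The other 5 of the 12 largest rises were the uncharacterised AT3G09450 (1.502 ± 0.203), AT5G40450 (1.06 ± 0.21), AT2G12905 (1.05 ± 0.19) and AT4G26950 (1.04 ± 0.10), and the transferase family gene AT1G31490 (1.03 ± 0.14).

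Among the falls, AT4G33467, which encodes an unknown protein (chromosome 4, 16101694 to 16102087), showed the largest log2 difference, -3.28 ± 0.64 (adjusted p = 0.038). It was well above background on 12 ambient arrays but on only 6 of the 12 elevated ones. DREB19, a transcription factor gene of the drought-related DREB family (AT2G38340, chromosome 2, 16074525 to 16075259), fell by 2.18 ± 0.42 and was likewise above background on 6 elevated arrays. The trypsin inhibitor gene TI1 (AT2G43510, chromosome 2, 18074288 to 18074697) fell by 1.78 ± 0.29. The DNAJ-domain gene AT1G56300 fell by 1.71 ± 0.19, above background on 7 elevated arrays. The GDSL esterase gene CDEF1, named for its effect on the cuticle (AT4G30140), fell by 1.198 ± 0.199. The pathogenesis-related gene PRB1 fell by 1.13 ± 0.20, and AT4G30660, annotated as responsive to low temperature and salt, fell by 1.15 ± 0.15. The remaining falls were those of AT4G22485, a protease inhibitor or lipid transfer family gene (-1.66 ± 0.29), AT3G05727 (-1.40 ± 0.28), the alcohol oxidase-related AT1G03990 (-1.29 ± 0.26, above background on 1 elevated and 8 ambient arrays), the putative phosphoglucomutase gene AT1G70820 (-1.17 ± 0.24) and the cysteine protease gene AT5G04250 (-1.13 ± 0.13). With normexp background correction, AT1G03990 (-0.17, adjusted p = 0.979), DREB19 (-1.04, 0.117), AT5G04250 (-0.65, 0.111) and AT1G56300 (-0.85, 0.0515) no longer passed, and AT4G33467 (-1.97), ORA59 (0.96) and PRB1 (-0.70) passed with smaller differences. The share of probes well above background was itself lower in elevated CO2, from 52.9% to 59.6% of an array against 56.5% to 64.7% in ambient CO2. The falls of the dim probes of AT4G33467, DREB19, AT1G56300 and AT1G03990 went the same way as this share. CO2 level and scan day were partly confounded. On the day that held both CO2 levels of Bur-0 and Col-0 the elevated arrays were replicate 2 and the ambient arrays replicate 1, so that CO2 level and replicate number could not be separated there. The scan day block also draws on these arrays. With scan day as a block the differences of BEE3 (0.60), AT2G12905 (0.58) and AT1G03990 (-0.83) were smaller by more than 1.5 times. With slide as a block 8 were: CDEF1 (-0.17), AT4G22485 (-0.72), AT3G05727 (-0.56), PRB1 (-0.50), AT1G03990 (-0.49), AT2G12905 (0.48), NRT1.5 (0.64) and AT1G56300 (-1.10). DREB19 (-3.93) and TI1 (-2.69) were larger by as much. All 24 named genes kept their sign with scan day or slide as a block and within the day that held both CO2 levels of Te-0 and Yeg-1, and 23 did within the day that held both of Bur-0 and Col-0, the exception being AT2G12905 at -0.01. Some differences within a day were much smaller, such as BEE3 (0.10) for Te-0 and Yeg-1 and ACO1 (0.19) and AT1G03990 (-0.14) for Bur-0 and Col-0. The 24 had been chosen for 1 sign in all 6 ecotypes, so that kept signs were partly built in. The 96 genes had been called with these arrays included, so that their signs within a day, kept by 95 of 96 on each, were partly built in. Of 100 genes with the smallest p in the 4 ecotypes not compared on that day, 89 kept their direction in Te-0 and Yeg-1 and 94 in Bur-0 and Col-0, against 60.4% and 62.8% of all genes. Their median log2 difference in that direction was 0.36 in Te-0 and Yeg-1, against 1.13 in the ecotypes of choice. In Bur-0 and Col-0 it was 0.66 against 0.79. The count of genes was 33 with scan day as a block (30 up, 3 down, 14 of them among the 96), and CER4, AT3G09450, AT4G26950 and PIL1 were the named genes that then passed. With scan day as a block and the labels of the 2 arrays exchanged, the count was 345 (284 up and 61 down, 42 of them among the 96). The count was 0 with slide as a block and the arrays as labelled (1761 genes at an unadjusted p under 0.05). The 1 slide with both CO2 levels of 1 ecotype held Yeg-1, and its Yeg-1 ambient array was 1 of the 2 that resembled the other ecotype. The slide block was not fitted with the labels exchanged. The count was also 0 with CO2 level by replicate number as a random block (524 at an unadjusted p under 0.05, fewer than a share of 0.05 of the genes). With replicate number as a block it was 567, and with that block within ecotypes 224. It was 71 without the 2 arrays that resembled the other ecotype and 281 with their labels exchanged, of which 95 were among the 96. Without the 2 arrays 10 of the 24 named genes did not pass: FTM1, AT5G40450, ACO1, AT4G33467, DREB19, AT4G22485, AT3G05727, AT1G03990, AT1G70820 and PRB1 (adjusted p from 0.0501 to 0.112). Leaving out 1 array at a time moved the count by more than 1.5 times for 19 of the 24 arrays. The count was highest without Te-0 ambient CO2 replicate 2, where the only Te-0 ambient array left was the one that resembled the other ecotype.

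**Figure D2:**
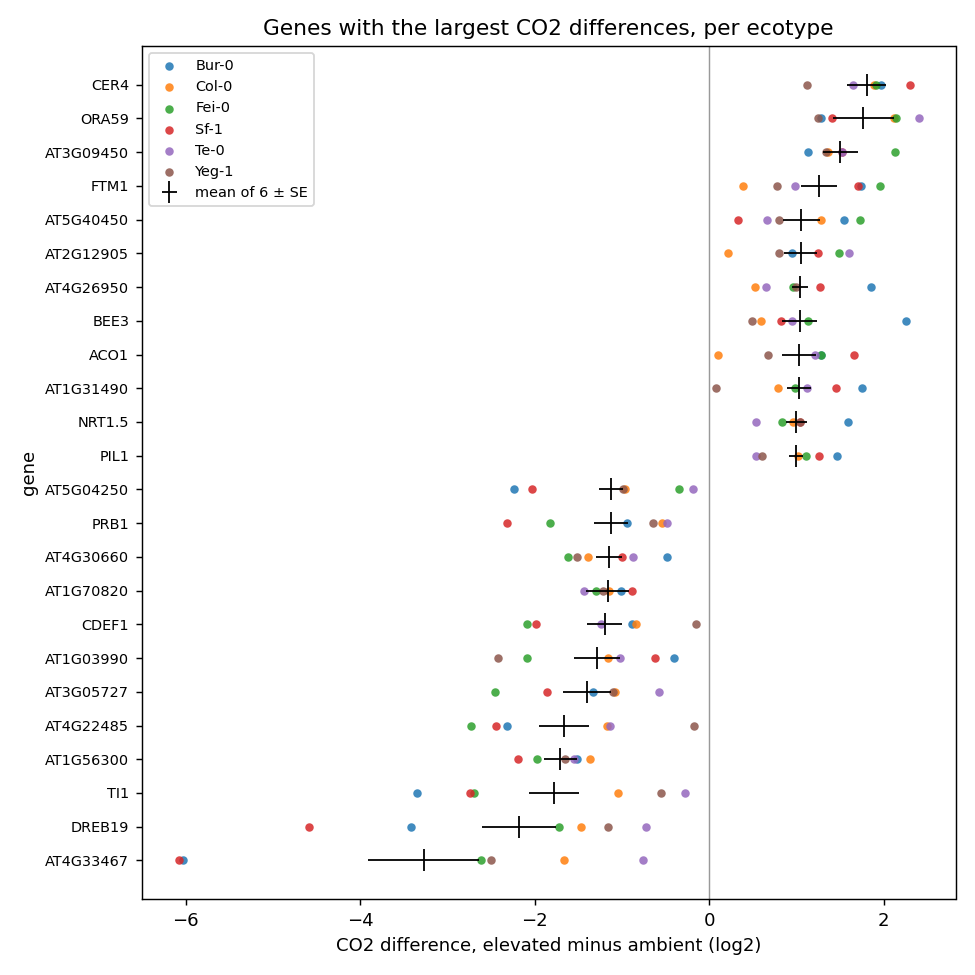
Log2 difference between elevated and ambient CO2 for the 12 largest rises and 12 largest falls that passed and had the same sign in all 6 ecotypes; coloured points are the 6 ecotypes (2 arrays per CO2 level each) and black marks the mean with its standard error from the linear model. CER4 has the largest mean rise, 1.81, and AT4G33467 the largest mean fall, -3.28. All arrays are used as labelled.

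Groups of genes fixed in advance were examined under the same contrast. In the nitrogen list, 2 of 28 measured members rose, NRT1.5 and the nitrate transceptor gene NRT1.1 (0.83 ± 0.12, adjusted p = 0.0091), and 26 did not pass. Adjusted over the list alone 3 passed. The list as a whole was not called (median 0.05, camera adjusted p = 0.277), while fry gave adjusted p = 1.27e-04 for change in either direction. In starch synthesis, APL3, a subunit of ADP-glucose pyrophosphorylase, rose by 0.43 ± 0.09, and 17 of 18 members did not pass (1 passed adjusted over the list alone; list median -0.06, adjusted p = 0.446); with normexp, APL3 had adjusted p = 0.103. In starch degradation, CT-BMY, the chloroplast beta-amylase gene also called BAM3, rose by 0.61 ± 0.12, and the other 17 of 18 members did not pass over all genes. Adjusted over the list alone, 10 members passed, 2 up and 8 down; ISA3 (-0.47), DPE2 (-0.52), PHS2 (-0.82) and the starch kinase gene SEX1 (-0.41) were lower in all 6 ecotypes. The starch degradation list was lower than other genes (median -0.25, camera adjusted p = 0.0155), with adjusted p = 0.813 with an estimated correlation. Fry had adjusted p = 0.0032 for change in either direction. In the sucrose and trehalose-6-phosphate list, the sucrose phosphate synthase gene ATSPS4F rose by 0.81 ± 0.17, 19 of 20 did not pass, 3 passed adjusted over the list alone (1 up, 2 down), and the list was not called (median -0.07, adjusted p = 0.269; fry in either direction, 0.0025). ATSPS4F had adjusted p = 0.0515 with normexp. The circadian clock list moved in both directions. The morning gene LHY rose by 0.97 ± 0.18 in the average over ecotypes and was higher in all 6 (adjusted p = 0.0372, and 0.0464 with scan day as a block), and the other 13 of 14 members did not pass over all genes. Adjusted over the list alone 5 clock genes passed: LHY, CCA1 (0.66) and RVE8 (0.62) up, PRR5 (-1.21) and ELF4 (-1.10) down. The list had fry adjusted p = 1.27e-04 for change in either direction, and camera, which asks for 1 direction against other genes, did not call it (median -0.13, adjusted p = 0.726).

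Camera called 7 of 25 lists, with the direction of the list against other genes (8 with the labels of the 2 arrays exchanged, 7 without them). Sugar starvation genes, which are induced when carbon is short, were lower, with all 14 members negative (median -0.29, adjusted p = 0.0016, and adjusted p = 0.382 with an estimated correlation). None of them passed over all genes or adjusted over the list alone. By ecotype, as labelled, the median was -0.67 in Bur-0, -0.62 in Sf-1 and -0.23 in Fei-0. It was 0.11 in Col-0, -0.02 in Te-0 and -0.13 in Yeg-1. Leaf senescence genes were lower (median -0.41, adjusted p = 0.0034, and adjusted p = 0.44 with an estimated correlation). Most of this fall was in 3 ecotypes, with medians of -1.92 in Sf-1, -0.60 in Bur-0 and -0.53 in Fei-0. The medians were -0.01 in Col-0, -0.14 in Te-0 and -0.01 in Yeg-1, as labelled. NYC1, a chlorophyll b reductase, fell by 0.45 ± 0.09 (adjusted p = 0.118 with normexp), 9 of 10 did not pass, and 4 passed adjusted over the list alone, all down, among them SAG12 (-2.57) and SAG29 (-2.20). Cold and drought response genes were lower, with 9 of 9 negative (median -0.57, adjusted p = 8.13e-05, and adjusted p = 0.355 with an estimated correlation). None passed over all genes and 5 passed adjusted over the list alone, such as COR47 (-0.57) and COR15B (-1.30). Iron homeostasis genes were higher (median 0.32, adjusted p = 0.0032, and adjusted p = 0.355 with an estimated correlation), with 0 of 18 passing over all genes and 2 adjusted over the list alone, PYE (0.37) and YSL1 (0.35). Photorespiration genes were slightly higher (median 0.12, adjusted p = 0.0336, and adjusted p = 0.813 with an estimated correlation; 0.117 relative to all genes in the unscaled series matrix, where the median itself was -0.12), with 0 of 20 passing and SHM2 (0.26) passing adjusted over the list alone. Cell cycle and DNA replication genes were slightly lower (median -0.15, adjusted p = 0.0078, and adjusted p = 0.813 with an estimated correlation; 0 of 22 passing, 0 adjusted over the list alone). Fry called none of the lists for movement 1 way; for change in either direction its adjusted p was 0.0458 for sugar starvation, 0.0235 for senescence and iron and 0.0275 for cold and drought. With scan day as a block the medians were 0.02 for starch degradation, -0.54 for sugar starvation, -0.68 for senescence, -0.21 for cold and drought, 0.20 for iron, 0.44 for photorespiration and -0.15 for cell cycle. The calls of starch degradation (adjusted p = 0.815), iron (0.319) and cold and drought (0.183) ended. Within the day with Te-0 and Yeg-1 the same medians were -0.10, -0.12, -0.15, -0.79, 0.29, 0.28 and -0.01, and within the day with Bur-0 and Col-0 they were 0.06, -0.46, -0.67, 0.04, 0.42, 0.45 and -0.25; with slide as a block they were -0.06, -0.52, -1.47, -0.20, 0.04, 0.50 and -0.14. Without the 2 arrays that resembled the other ecotype, photorespiration had adjusted p = 0.628.

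**Figure D3:**
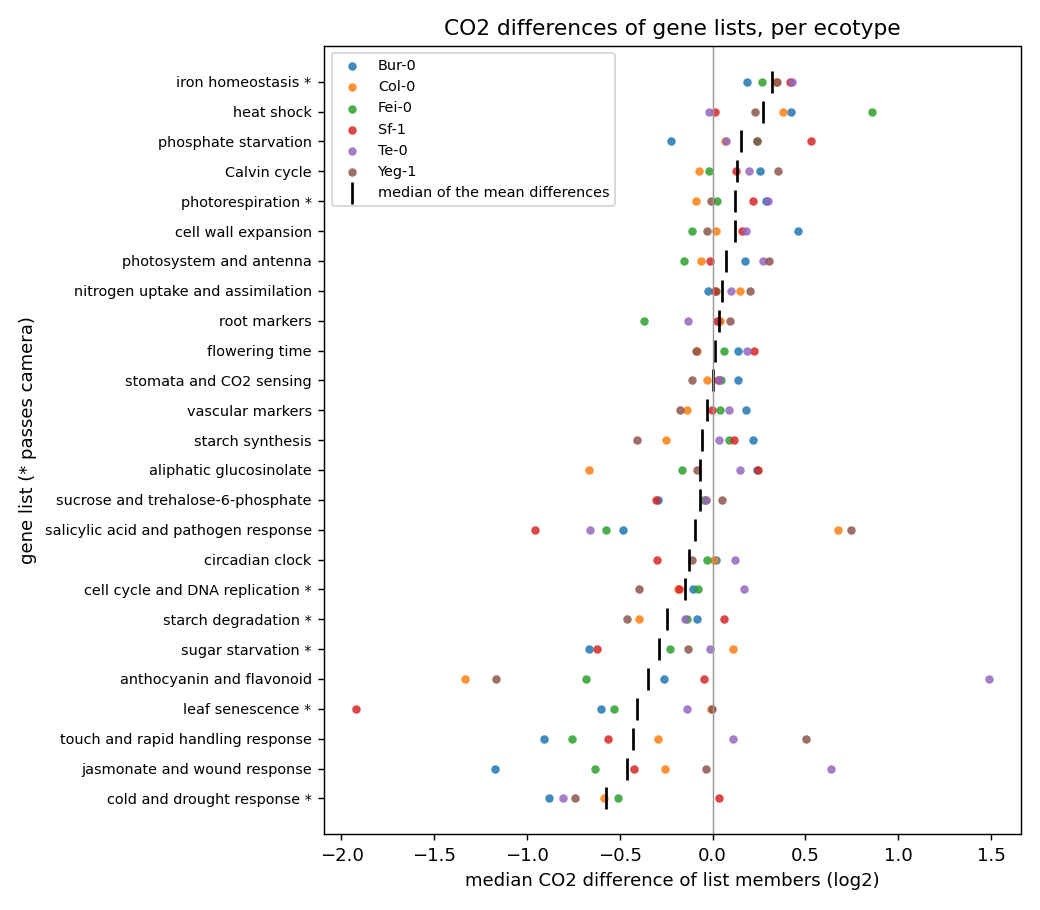
Median log2 difference between elevated and ambient CO2 over the members of each of the 25 tested lists; coloured points are single ecotypes and the black bar is the median over members of the mean difference over 6 ecotypes, with an asterisk where camera called the list. The cold and drought list has the lowest median, -0.57, and the iron list the highest, 0.32. All arrays are used as labelled.

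The other lists were not called. Their medians were 0.07 for photosystem and antenna genes (adjusted p = 0.297), 0.13 for the Calvin cycle (0.127), -0.35 for anthocyanin and flavonoid genes (0.164), -0.10 for salicylic acid and pathogen response (0.133), -0.46 for jasmonate and wound response (0.0873), -0.07 for aliphatic glucosinolates (0.472), 0.12 for cell wall expansion (0.269), 0.01 for flowering time (0.477), 0.00 for stomata and CO2 sensing (0.718), 0.15 for phosphate starvation (0.215), 0.27 for heat shock (0.277) and -0.43 for touch and rapid handling (0.257). Camera called anthocyanin and flavonoid genes lower with the labels of the 2 arrays exchanged (adjusted p = 0.0379) and without these arrays (0.0091). As labelled, they had adjusted p = 0.813 with an estimated correlation. With scan day as a block their median was 0.40 (adjusted p = 0.223). The labels do not say which organs were harvested, and markers of other organs were also followed. Root markers had a median of 0.03 (adjusted p = 0.806) and vascular markers one of -0.03 (0.718). Camera gave root markers the direction down, against the sign of their median and mean, and the vascular mean was positive, 0.005. Only 3 of 8 flower markers were measured, too few for the test, with a median of 0.40 and none passing. None of these lists had a member past the threshold over all genes. With scan day as a block, camera called photosystem and Calvin cycle genes higher (medians 0.37 and 0.41, adjusted p = 6.61e-08 for both, and adjusted p = 0.618 and 0.268 with an estimated correlation). Under that block it also called cell wall genes higher (0.39, adjusted p = 0.01, and 0.268 with an estimated correlation) and salicylic acid genes lower (-0.58, adjusted p = 3.52e-05, and 0.632 with an estimated correlation).

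The second comparison took each ecotype by itself, with 2 arrays per CO2 level. In Bur-0, 6 genes passed, 3 up and 3 down. The sugar-related genes SIP2, a raffinose-hydrolysing galactosidase (AT3G57520, chromosome 3, 21299959 to 21303671), and ESL1, a putative sugar transporter (AT1G08920, chromosome 1, 2867449 to 2870363), fell by 2.79 ± 0.36 and 2.37 ± 0.31 (both adjusted p = 0.0122), and AT5G04250 fell by 2.24 ± 0.33. AT4G26950 and PIL1 rose by 1.85 ± 0.23 and 1.47 ± 0.20, and AT3G62110, a polygalacturonase-like gene, rose by 1.08 ± 0.15. None of the 6 passed on the 4 Bur-0 arrays alone, with array weights or with replicate number as a block within ecotypes, where the Bur-0 count was 0. It was 15 with replicate number as a block over all arrays. No gene passed in the other 5 ecotypes with limma. With replicate number as a block, 8 genes passed in Sf-1 and 1 in Col-0, and with that block within ecotypes 4 passed in Sf-1. In Sf-1, 22 passed on its own 4 arrays, 26 with array weights and 5 with the labels of the 2 arrays exchanged. In Col-0, 3 passed with the labels exchanged and 3 without the 2 arrays. Over genes, the replicate deviations of elevated and ambient arrays correlated by 0.31 to 0.45 in 5 of the 6 ecotypes, a pairing that the labels do not state. At an unadjusted p under 0.05 there were 228 genes in Col-0, 376 in Fei-0, 1005 in Sf-1, 474 in Te-0, 1497 in Yeg-1 and 986 in Bur-0. In Te-0 there were 142 with the labels of the 2 arrays exchanged and 195 without them, and in Yeg-1 1101 and 538. With no CO2 difference, a share of 0.05 of the 19972 genes tested would be expected. Col-0, Fei-0 and Te-0 were under that share, and Sf-1 and Bur-0 close to it. Yeg-1 was over it as labelled and exchanged, and under it without the 2 arrays. Counts at or under the share show no excess of small p. They go with tests that call few genes, so a lack of calls does not show a lack of response. The genes with the 2 smallest p in each of the 5 ecotypes other than Bur-0 did not pass. In Col-0 they were AT5G37560, a zinc-binding protein gene that was not well above background on the ambient arrays and at least 19.8-fold higher in elevated CO2 (adjusted p = 0.0976, 0.0038 with the labels exchanged and 0.0155 without the 2 arrays), and PIL1 (1.01 ± 0.20). In Fei-0 they were PIL1 (1.11 ± 0.20) and AT5G47620 (0.86 ± 0.20), and in Sf-1 PIL1 (1.25 ± 0.20) and AT5G04250 (-2.03 ± 0.33, adjusted p = 0.103 for both; 0.047 for PIL1 with the labels exchanged). In Te-0 they were AT3G58340 (at least 3.96-fold higher) and NRP1 (-0.94 ± 0.21), and in Yeg-1 AT3G45440 (at least 2.56-fold lower) and AT2G02770 (at least 3.86-fold lower). The fitted difference of AT2G02770 was -3.68 as labelled, -2.49 without the 2 arrays and -2.23 with them exchanged, and that of AT3G45440 was -2.59, -2.13 and -1.90. The Bur-0 count was 17 with the labels of the 2 arrays exchanged and 1 with slide as a block, and leaving out 1 of its own arrays gave 2 or 0 without elevated CO2 replicate 1 or 2, and 26 or 30 without ambient CO2 replicate 1 or 2. Leaving out ambient CO2 replicate 2 of Te-0 or Yeg-1 could not show a CO2 difference there. The only ambient array left was then the one that resembled the other ecotype. No gene had a CO2 difference that depended on the ecotype by the limma F test of the interaction (222 at an unadjusted p under 0.05; 2 genes passed with the labels exchanged and 3 without both arrays), so the single-ecotype counts do not show that ecotypes differed. The 222 genes are also fewer than the share of 0.05 expected with no difference.

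The third comparison asked whether the response to CO2 differed between ecotypes whose growth was enhanced more and those enhanced less. Each ecotype gave 1 value, so 3 ecotypes stood against 3. No gene passed (limma; 2110 at an unadjusted p under 0.05; 4 passed without the 2 arrays that resembled the other ecotype). The genes with the smallest p, none of which passed (adjusted p = 0.44 for each), included GRX480, a glutaredoxin gene of the salicylic acid response, whose CO2 difference was 2.35 ± 0.30 log2 units lower in the larger-enhancement class (-2.35), the glutamine amidotransferase-like GAT1_2.1 (-3.08 ± 0.42; adjusted p = 0.0446 without the 2 arrays), the glycosyltransferase gene UGT76E1 (-2.58 ± 0.36), the lectin kinase gene AT3G59730 (-1.54 ± 0.20) and the glutaredoxin family gene AT4G15690 (-1.03 ± 0.13). Fitted differences for AGL42 (1.77 ± 0.25), AT2G45161 (1.79 ± 0.23) and CRP4 (1.17 ± 0.15, and 2.18 without the 2 arrays) were positive, but their probes were mostly not above background, on 4, 3 and 5 of the 12 arrays of the larger-enhancement class and 4, 6 and 5 of the 12 of the other. AT3G59730 was above background on 3 and 6 of these arrays and GAT1_2.1 on 10 and 6. The probes of CRP4 and AT4G15690 carry a predicted cross-hybridisation. In the gene lists, camera called 8 of 25 (8 with the labels exchanged, 11 without the 2 arrays). The salicylic acid and pathogen response list had the most negative median, -1.19, with all 20 members negative (adjusted p = 2.88e-09, and adjusted p = 0.4 with an estimated correlation). PR1 differed by -1.23 in Bur-0, -3.28 in Fei-0 and -2.83 in Sf-1, against 1.64 in Col-0, -1.26 in Te-0 and 0.96 in Yeg-1. In the same order WRKY70 differed by -0.03, -0.47 and -0.95 against 0.67, 1.05 and 0.61. The Te-0 and Yeg-1 values use the 2 arrays that resembled the other ecotype as labelled. None of the 20 members passed over all genes, and 3 did adjusted over the list alone, all down. Jasmonate and wound response (median -0.84, 18 of 18 negative, adjusted p = 9.46e-05, and adjusted p = 0.4 with an estimated correlation) and touch and rapid handling genes (median -0.90, 6 of 6 negative, adjusted p = 0.004, and adjusted p = 0.4 with an estimated correlation) also had lower CO2 differences in the larger-enhancement class. So had sugar starvation (-0.46, adjusted p = 0.0031), nitrogen (-0.11, 0.0295) and photosystem genes (-0.13, 0.0065). With an estimated correlation, adjusted p = 0.4 for sugar starvation and nitrogen and 0.746 for photosystem genes. Starch synthesis (0.39, 17 of 18 positive, adjusted p = 0.0011) and starch degradation (0.24, 16 of 18 positive, adjusted p = 0.0448) had higher ones. With an estimated correlation, adjusted p = 0.485 for starch synthesis and 0.452 for starch degradation. Fry called none for movement 1 way. No scan day held both CO2 levels of Fei-0 or Sf-1, so these differences could not be set within a day.

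The same 2 classes were compared in expression level. Probes were designed on the Col-0 reference, and Col-0 is in the smaller-enhancement class. A weaker match of probes to the other ecotypes could therefore also lower the signal of the larger-enhancement class. Sequence differences were not examined. In elevated CO2, 3 genes passed, all lower in the larger-enhancement class and not well above background on any of its 6 arrays: AT4G10800 was at least 21.5-fold lower, AT5G03495, a nucleotide-binding protein gene, at least 12.9-fold lower, and AT3G08980, a signal peptidase family gene, at least 9.65-fold lower (adjusted p = 0.02 for each). The next 5 genes by p did not pass: AT3G50880 (-2.06 ± 0.17), EIF4B1 (-1.61 ± 0.13), AT2G05320 (at least 6.29-fold lower), AT5G57890 (-2.05 ± 0.18) and AT5G56100 (-1.78 ± 0.17). In ambient CO2, 12 genes passed, again all lower in the larger-enhancement class. They included AT4G10800 (-5.79 ± 0.23, adjusted p = 0.0046), AT5G03495 (-5.45 ± 0.39) and AT2G05320 (-3.98 ± 0.30), each above background on 1 of 6 arrays of the larger class, and AT3G08980 (at least 13.2-fold lower). The chromatin protein gene HMGB6 (-3.88 ± 0.32), the receptor kinase gene AT5G45840 (-2.65 ± 0.19), the translation initiation factor gene EIF4B1 (-1.95 ± 0.12), the DNA repair family gene AT3G50880 (-1.92 ± 0.17), AT3G46490 (-2.49 ± 0.19) and AT5G22520 (at least 4.01-fold lower, above background on 4 of 6 arrays of the smaller class) were among the 12. Of these 10 named genes only AT4G10800 and AT3G08980 passed without the 2 arrays that resembled the other ecotype (adjusted p = 0.0094 and 0.0204), and with the labels exchanged also EIF4B1 (0.0438). AT3G46490 and AT5G22520 had adjusted p = 0.699 and 0.895 without these arrays and 0.999 with the labels exchanged. Without Col-0 the ambient count was 107, 76 higher and 31 lower, and without Te-0 or Yeg-1 it was 0. As labelled, the ambient means of Te-0 and Yeg-1 each average an array that resembled Te-0 and an array that resembled Yeg-1. This draws 2 of the 3 values of the smaller class together and lowers the spread within that class. The ambient counts of 12 and 107 rest partly on this lowered spread. AT5G22520, for example, had an SD of 3.70 over the 6 arrays of the smaller class but a standard error of 0.32. The ambient count was 2 without the 2 arrays that resembled the other ecotype and 3 with their labels exchanged, and the elevated count, which uses neither array, was 3 in both. Without Col-0 the elevated count was 1, a gene higher in the larger-enhancement class, and without Yeg-1 it was 10, 2 higher and 8 lower. It was 0 without Bur-0 or Te-0, 1 without Fei-0 and 7 without Sf-1. With only probes well above background on all 24 arrays it was 0, and the ambient count was 7. Leaving out 1 array gave an ambient count of 4 without Te-0 replicate 2 or Yeg-1 replicate 1, 5 without Bur-0 replicate 2, 6 without Sf-1 replicate 2 and 7 without Te-0 replicate 1, and an elevated count of 0 without replicate 1 of Sf-1 or Bur-0 and 6 without Col-0 replicate 2.

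Camera called 10 lists for level in elevated CO2 and 5 in ambient CO2, the latter 7 with the labels of the 2 arrays exchanged and 10 without them. Among the 10 splits of the 6 ecotypes into 3 and 3, the highest other split called 7 lists in elevated and 8 in ambient CO2. As many lists as in the real split were called by 1 of 10 splits in elevated and 5 of 10 in ambient CO2, the real one included. In elevated CO2 the larger-enhancement class was lower in photosystem (median -0.26, adjusted p = 1.84e-06), Calvin cycle (-0.14, 0.04), sugar starvation (-0.21, 0.04), salicylic acid (-0.89, 20 of 20 negative, 5.38e-04), jasmonate (-0.18, 0.0407) and iron genes (-0.19, 0.04), and higher in starch synthesis (0.34, 0.005), aliphatic glucosinolate (0.54, 0.0125), stomata (0.18, 0.0447) and vascular genes (0.29, 0.04). With an estimated correlation the adjusted p of these 10 lists was 0.543 for starch synthesis, jasmonate, glucosinolate, iron and vascular genes, 0.575 for photosystem, 0.606 for stomata, 0.628 for salicylic acid and sugar starvation and 0.715 for the Calvin cycle. In ambient CO2 it was lower in photosystem (-0.08, 0.0243) and photorespiration genes (-0.14, 7.82e-04) and higher in jasmonate (0.44, 0.0081), cell cycle (0.16, 0.0243) and touch genes (1.04, 6 of 6 positive, 7.82e-04). With an estimated correlation the adjusted p was 0.942 for photosystem genes and 0.906 for the other 4. Class and scan day were partly confounded in ambient CO2, for genes as for lists. The replicate 1 ambient arrays were scanned on day 2 for Fei-0 and Sf-1, day 1 for Te-0 and Yeg-1 and day 3 for Bur-0 and Col-0. The elevated arrays of both classes shared their scan days. Vascular genes, markers of another tissue, thus stood higher in the larger-enhancement class in elevated CO2, beside the lists named here.

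The last comparison asked how the ecotypes differed in expression, whatever the CO2 level. The F test over 6 ecotypes called 4797 genes, 24.0% of those tested, and 1781 of the called genes spanned more than 2 log2 units between the highest and lowest ecotype. In the aliphatic glucosinolate list, which makes and breaks down mustard oil glucosides, 16 of 22 members differed. The glucoside-modifying gene AOP2 was at 1.97 in Col-0 and from 6.17 to 6.80 in the other 5 (normalized log2 signal, n = 4 arrays per ecotype, adjusted p = 1.12e-07). The myrosinase gene TGG2 was at -1.50 in Bur-0 and from 4.55 to 5.79 elsewhere. ESM1 was at 6.25 in Col-0 and from -1.72 to 2.62 elsewhere, and ESP at 3.55 in Col-0 and 8.26 in Sf-1. In the flowering time list 8 of 13 differed. FLC, the repressor of flowering, was at -0.05 in Col-0 and 0.68 in Bur-0 and from 2.64 to 3.59 in the other 4 (adjusted p = 1.81e-07), and its relative MAF3 from -0.41 to 1.29 in Bur-0, Col-0 and Fei-0 and from -7.39 to -5.90 in Sf-1, Te-0 and Yeg-1. SARD4, of the salicylic acid list, was at -5.16 in Bur-0 and from -0.84 to 0.43 elsewhere. A probe that matches an ecotype's sequence less well also reads lower, so these are levels of probe signal.

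Against the mean of the other 5, Bur-0 had 2156 genes past the threshold, Sf-1 2084, Col-0 1914, Fei-0 1735, Yeg-1 1038 and Te-0 868. With the labels of the 2 arrays exchanged the order changed, to 4238 in Yeg-1, 3405 in Te-0, 3175 in Bur-0, 3091 in Sf-1, 2824 in Col-0 and 2646 in Fei-0. In Bur-0, SVL2, a glycerophosphodiester phosphodiesterase family gene, was at least 476-fold lower and AT4G34920, a phosphatidylinositol phosphodiesterase-related gene, at least 135-fold lower. AT4G08874 was at least 157-fold higher and AT3G22235 higher by 8.69 ± 0.46 log2 units. In Col-0, the thionin gene AT1G66100 was at least 589-fold and AT1G76960 at least 231-fold higher, AT4G32230 at least 16.4-fold lower, and AT3G48640, above background on 1 of 4 Col-0 arrays, had a fitted difference of -5.9997 ± 0.5228. In Fei-0, AT5G19750, a peroxisomal membrane family gene, was at least 448-fold lower and UBQ11, above background on 1 of 4 Fei-0 arrays, had a fitted difference of -10.66 ± 0.32, while AT2G36540 and the plastid ribosomal protein gene PSRP6 were higher by 9.36 ± 0.55 and 9.26 ± 0.66. In Sf-1, the terpene synthase gene AT4G20210 was at least 111-fold higher, the ribosomal protein gene AT2G47570, above background on 1 of the 20 other arrays, had a fitted difference of 8.38 ± 0.50, and AT5G38980 and the histone H4 gene AT3G53730 were at least 257-fold and 243-fold lower. In Te-0 and Yeg-1, AT4G07868 was higher by 7.05 ± 0.53 and 6.88 ± 0.53. Te-0 was also higher in AT2G27540 (6.58 ± 1.60; predicted cross-hybridisation) and lower in the xyloglucan-modifying XTH7 (-8.574 ± 1.797, above background on 1 of 4 Te-0 arrays) and the calcium-binding AT2G41090 (-7.81 ± 1.90), and Yeg-1 was higher in AT1G03106 (5.36 ± 1.44) and lower in AT5G42530 (-6.76 ± 1.79) and in TAF7 (at least 40.3-fold). Several of the genes higher in 1 ecotype were dim in most others: AT3G22235 and AT4G07868 were above background on 8 of the 20 other arrays, PSRP6 on 6, AT2G27540 and AT1G03106 on 5 and AT2G36540 on 11. The size of their differences rests largely on signal near background. Among the genes that were lower, AT4G32230 was above background on 13 of the 20 other arrays, TAF7 on 16 and AT3G53730 on 17. With the labels of the 2 arrays exchanged the last-named values became 10.20 for AT2G27540, -12.43 for XTH7, -11.88 for AT2G41090, 8.15 for AT1G03106 and -10.46 for AT5G42530, and the F test called 7945 genes, 4781 of them among the 4797; it called 2368 with slide as a block.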

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

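The fit of the unannotated transcription units was chosen after the data were examined; the list tests were planned. The array also carries probes for transcription units without a gene annotation, which the comparisons of genes leave out. Of 1632 such units that passed the filter, 427 differed between ecotypes by the limma F test (26.2%, against 24.0% of annotated genes), a signal in data outside the main measurement. None passed for the mean CO2 difference (limma; 80 at an unadjusted p under 0.05, 4 called with the labels of 2 arrays exchanged and 1 without these arrays). The 80 units are near the share of 0.05 expected with no difference.

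The CO2 difference of 8 gene lists differed between the growth classes by camera. With an estimated correlation 0 of the 8 lists passed (limma camera; 2 had an unadjusted p under 0.05, touch at 0.0265 and nitrogen at 0.0487). The medians of larger-enhancement minus smaller-enhancement class were -1.19 for the salicylic acid and pathogen response list, -0.90 for touch and rapid handling, -0.84 for jasmonate and wound response, -0.46 for sugar starvation, -0.13 for photosystem and antenna, -0.11 for nitrogen, 0.24 for starch degradation and 0.39 for starch synthesis. Of the 10 splits of the 6 ecotypes into 3 and 3, only the real one, 1 of 10, called as many lists, and the highest other called 6, but 10 splits are too few for a share under 0.05. No technical or biological explanation was tested.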

How the results depend on the processing

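The tests with the 2 arrays left out or exchanged, and with scan day as a block for the lists, alone or with an estimated correlation, were chosen after the data were seen. The mean CO2 difference kept its count of 96 genes within 1.5 times with normexp (73), quantile normalization (131), the strict filter (101), no trend (79), outlier spots left out (96), without Col-0 (64), Te-0 (105) or Yeg-1 (68) and without both arrays (71). It moved to 20 with the series matrix (1 up, 19 down), whose unscaled values lower all genes, 42 with no filter, 567 with a replicate block, 224 with that block within ecotypes, 33 with scan day and 0 with slide as a block, 0 with the random block, 49 with array weights, 10 without Bur-0, 17 without Fei-0, 10 without Sf-1 and 0 with 1 value per ecotype (3088 at an unadjusted p under 0.05). It was 281 with the labels exchanged, which leaves the mean difference as it was and lowers the spread, and 345 with exchange and scan day together. Leaving out 1 array gave 27 (Fei-0 ambient replicate 1) to 265 (Te-0 ambient replicate 2). The other moves beyond 1.5 times were 29 without Sf-1 elevated replicate 2, 38 without Col-0 ambient replicate 1, 39 without Yeg-1 elevated replicate 2, Fei-0 ambient replicate 2 or Bur-0 elevated replicate 2, 40 without Sf-1 ambient replicate 2, 41 without Te-0 elevated replicate 2 or Col-0 ambient replicate 2, 44 without Fei-0 elevated replicate 2, 47 without Sf-1 ambient replicate 1, 55 without Yeg-1 ambient replicate 2, 56 without Bur-0 elevated replicate 1, 57 without Yeg-1 elevated replicate 1 or Sf-1 elevated replicate 1, 58 without Te-0 elevated replicate 1, 63 without Te-0 ambient replicate 1 and 152 without Bur-0 ambient replicate 1. For Bur-0 the count of 6 moved to 0 with the series matrix, the replicate block within ecotype, array weights and its own 4 arrays alone, to 15 with the replicate block, 1 with slide, 17 with exchange and 263 with exchange and scan day, and leaving out 1 array gave 0 to 30. For Col-0 the count of 0 moved to 3 with quantile normalization, without both arrays, with exchange and with exchange and scan day, to 2 with the series matrix and to 1 with no trend, the replicate block, scan day, array weights and its own 4 arrays (0 to 4 without 1 array). For Sf-1 it moved from 0 to 1 with normexp and with quantile normalization, 8 with the replicate block, 4 with that block within ecotype, 26 with array weights, 22 with its own 4 arrays, 5 with exchange and 3 with exchange and scan day (1 to 4 without 1 array). Leaving out 1 array gave 0 to 2 in Fei-0, 0 to 53 in Te-0 and 1 to 36 in Yeg-1 (both highest without ambient replicate 2), where leaving out both arrays gave 1. The interaction moved from 0 to 3 without both arrays, 2 with exchange and 3 with exchange and scan day (0 to 3 without 1 array). The class difference in CO2 effect moved from 0 to 4 without both arrays (0 to 1 without 1 array). In level at elevated CO2 the class count of 3 moved to 0 with the strict filter, 6 with no trend, 0 without Bur-0, 1 without Col-0, 1 without Fei-0, 7 without Sf-1, 0 without Te-0, 10 without Yeg-1 and 1108 with arrays as replicates (0 to 6 without 1 array). At ambient CO2 that of 12 moved to 7 with the strict filter, 107 without Col-0 (76 higher, 31 lower), 0 without Te-0, 0 without Yeg-1, 868 with arrays as replicates, 2 without both arrays and 3 with exchange (4 to 14 without 1 array). The ecotype count of 4797 moved to 1576 with the series matrix, 7476 with the replicate block, 2368 with slide, 7564 with the random block, 3146 without Fei-0, 3048 without Sf-1, 7945 with exchange and 10896 with exchange and scan day. Gene lists called fell to 0 with an estimated correlation (camera; 3 and 2 at an unadjusted p under 0.05 in the first pair, 0 in the others), from 7 for the mean CO2 difference, 8 for the class difference in CO2 effect, 10 in level at elevated and 5 in level at ambient CO2. The last count rose to 10 without both arrays. With scan day as a block and an estimated correlation together, 0 lists passed for the mean CO2 difference (camera; 4 at an unadjusted p under 0.05). Among single genes named by the rule, control genes left out, none reversed in these fits, though within the day of Bur-0 and Col-0 alone AT2G12905 was at -0.01. Some control genes did change sign, as given below. With 1 array left out 1601 gene results kept their side of the threshold, 379 no longer passed and 4 newly passed, and under the other alternatives 1335, 451 and 21. The strict filter tests fewer genes and the fits without an ecotype use fewer arrays. Without ambient replicate 2 of Te-0 or Yeg-1, the only ambient array left there was the one that resembled the other ecotype. The counts without these arrays therefore mix ecotype with CO2. As labelled, the ambient values of Te-0 and Yeg-1 are also drawn together, which lowers the class spread behind the ambient class counts of 12 and 107. For the other moves the cause was not tested. Replicate numbers may mark shared units: the deviations of elevated and ambient arrays from their group means correlated over genes by 0.45 in Bur-0, 0.36 in Col-0, 0.32 in Fei-0, 0.39 in Sf-1, 0.31 in Te-0 and 0.04 in Yeg-1, and the random block had a consensus correlation of 0.296. A group with 1 array left was taken to vary like the others. The mean over probes of a locus was not run, as each locus has 1 probe, and the replicate block within ecotype could not be fitted for ecotype differences. Arrays with fewer probes well above background give less certain values for dim genes. This share was 52.9% to 59.6% on elevated and 56.5% to 64.7% on ambient arrays, so falls of dim genes went with it.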

Other observations

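The placement of the 2 arrays, the scan-day comparison and the share of low outlying ecotypes were tests chosen after related results had been seen. The random block was a planned setting, but its use to weigh growth units was chosen afterwards. The groupings of arrays were planned. Control genes did not pass for CO2. ACT2 and ACT8 were at 0.26 ± 0.12 and 0.23 ± 0.11 (adjusted p = 0.407 and 0.437), and in the unscaled series matrix, where the median of all genes was -0.24, at 0.02 and -0.02. SAND (0.16), EF1A (0.08, -0.04 with quantile normalization), TIP41 (0.03) and PP2AA3 (0.01, -0.0013 with normexp) did not pass either and were negative in the unscaled values, and nor did UBQ10 (-0.09) or GAPC1 (-0.07, 0.07 with normexp). Between ecotypes 3 of the 8 differed: UBQ10 by 3.61 log2 units from highest to lowest (adjusted p = 3.17e-04), GAPC1 by 1.89 and TIP41 by 0.54. Adjusted over the list alone, root markers moved both ways with CO2, PYK10 (-0.52) and WOX5 (-0.65) down and the iron reductase gene FRO2 (0.39) up, and none passed over all genes. The largest CO2 difference by p among unannotated units was that of NEW_TU_20 on chromosome 3, 14205360 to 14206582 (-1.06 ± 0.19, adjusted p = 0.0723).

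A first pattern is that the arrays labelled Te-0 ambient CO2 replicate 1 and Yeg-1 ambient CO2 replicate 1 each resembled the other ecotype. On 1075 genes chosen on the elevated CO2 arrays alone, the array labelled Te-0 lay at a median of 1.0426 of the way to the other ecotype and that labelled Yeg-1 at 0.9728, so a mixture of both RNAs, which would place them between, is argued against. The replicate 2 ambient arrays stayed with their own labels, the farther at 0.0831, which argues against a change of expression caused by ambient CO2. That the 2 arrays carry each other's label therefore may be the source, as a hypothesis, and the files alone do not show where labels or material were exchanged. With the labels exchanged, the correlation of replicate deviations over genes rose to 0.56 in Te-0 and 0.50 in Yeg-1.

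A second pattern is the set of genes that differed with CO2. Genes chosen in the 4 ecotypes not compared on that day kept their direction within a scan day in 89 of 100 cases for Te-0 and Yeg-1 and in 94 of 100 for Bur-0 and Col-0, against 60.4% and 62.8% of all genes. These directions argue against scan day as the whole cause. The median log2 difference in the chosen direction was smaller within a day. It was 0.36 in Te-0 and Yeg-1, against 1.13 in the ecotypes of choice, and 0.66 against 0.79 in Bur-0 and Col-0. A part due to scan day is not excluded. In Bur-0 and Col-0 that day set elevated replicate 2 against ambient replicate 1, so replicate number is not excluded there. In Te-0 and Yeg-1 all arrays of that day were replicate 1. With CO2 level by replicate number as a random block 0 genes passed, so a difference between growth units that hold all plants of 1 CO2 level and replicate cannot be told apart from CO2, since only 2 such units per level exist. Of 100 groupings within ecotypes 3, the real one included, called 96 or more genes. That share argues against chance only if the arrays vary independently. The groupings were drawn in each ecotype apart, which breaks up units shared by all ecotypes, so a chance difference between such units is not excluded. The grouping of replicate 1 against replicate 2 called 7169, which points to a structure of the samples that follows replicate and scan day. The count was 567 with replicate number and 33 with scan day as a block. With scan day as a block and the labels of the 2 arrays exchanged it was 345. The real CO2 response stays among the open explanations and may account for the pattern.

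Another pattern is that genes at least 16-fold apart from each of the other 5 ecotypes were mostly low in 1 ecotype, except in Col-0. The share that was lower was 87.8% in Bur-0, 85.3% in Fei-0, 76.9% in Sf-1, 72.7% in Te-0 and 100% in Yeg-1, where 5 of 5 genes were lower, but 8.82% in Col-0, where 3 were lower and 31 higher; with the labels of the 2 arrays exchanged it was 71.4% in Te-0 and 91.9% in Yeg-1. Probes designed on the Col-0 reference that match other ecotypes less well, or genes missing there, could produce this, and the share of 72.7%, the lowest of the 5, is what mismatch would need. Sequence differences were not examined, and real differences in expression stay open.

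For the other results, groupings gave the following. Of 100 groupings within ecotypes, 42 called at least the 7 gene lists of the mean CO2 difference, the highest other calling 11, so chance is not excluded for the number of lists. For the interaction the real count was 0 and the highest other 367; all 100 of 100 reach a count of 0 by construction, so this decides nothing. For ecotype differences 1 of 100 regroupings, the real one, called 4797 genes, the highest other 368, so chance is excluded. For the classes 10 splits are too few for a share under 0.05: the CO2 effect had 0 genes in all 10, the level in elevated CO2 3 genes, as many in 8 of the 10 and 10 in the highest other, and the level in ambient CO2 12 genes, as many in 2 of the 10 and 12 in the highest other.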
